A study of Mus musculus with 5 samples.

How the data were processed

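The series holds RNA-seq libraries of stromal cells from mesenteric adipose tissue of infected mice, 3 titled WT and 2 titled KO. Per the labels' protocols, RNA was isolated with a column kit, libraries were made with the NEBNext Single Cell/Low Input kit, which does not mark strand, and sequencing used an Illumina instrument. The authors deposited a single table of raw counts per gene, as whole numbers without normalization, under versioned Ensembl gene identifiers. Per the submitters' processing notes, STAR, featureCounts, DESeq2 and deepTools were used with the mouse build mm10, with no version or role for any of them. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Reads of near-identical paralogs and of overlapping genes on either strand can therefore be lost or be counted for the wrong gene.

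Of 47937 genes in the table, 47224 were matched to a symbol by their identifier without version, and 39192 carry the same version as in GENCODE M21, the annotation on the same build from which coordinates (counted from 1) were taken. Columns were joined to samples by the name in each sample's description. Library totals ran from 25645996 to 39222470 counts. At these depths 3 counts, the limit that a count of 0 allows, correspond to 0.0765 to 0.117 CPM per library, which covers counting error only. Without molecular identifiers, reads are not independent molecules. Libraries of a group were compared for duplication, and none was found, with a chi-square per degree of freedom of 12.2 or more for each pair. Pearson's r across genes, which are not independent replicates, lay between 0.978 and 0.990 for log2 CPM with a prior count of 2. The first principal component held 39.2% of the variance and placed both KO libraries (38.9 and 14.7) apart from the WT libraries (-27.0, -18.3 and -8.38). By Pearson's r, however, KO replicate 2 was no closer to KO replicate 1 (0.986) than to WT replicate 3 (0.988).

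Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were filtered with filterByExpr (minimum count 10, minimum total count 15), scaled with TMM factors (0.985 to 1.01) and tested with edgeR's robust quasi-likelihood test with the group as the single term, two-sided, with Benjamini-Hochberg adjustment over 14925 genes. The biological coefficient of variation was 0.129 with 3 residual degrees of freedom. Fits that leave out 1 library have fewer, so a gene can lose its call there through lost power alone. The standard error of a log2 fold change is its size divided by the square root of the F statistic. CPM values of genes are scaled by the TMM factors, and sums over marker lists use the library totals. Sums were compared with two-sided exact permutation tests, adjusted over the quantities tested (adjusted p = 0.3 for those at the smallest p). All 168 genes called and 4476 of the 14925 tested (30.0%) had no overlap between the groups, where chance gives 20%.

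The comparison, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. There were 38 lists, 20 for pathways, 15 for cell type markers and 3 for RNA quality. Of their 769 genes, 768 were in the table. The rule named Egfr, the 12 genes with the largest rise and the 12 with the largest fall among called genes with a regular symbol, at least 5 CPM in the higher group and no overlap between groups, and up to 4 called members of smallest p in each pathway list. Where a pathway list had no called member, up to 2 members of smallest p could be named, and for other lists up to 3 of the most abundant and up to 3 called members. Il33, Dpp4, Pi16, Ier3, Loxl4, Timp3 and the further genes named only in the closing section were chosen after their values were seen, and so was the count of fits that kept each named gene. A gene that the rule names is not reported here. Lists with at least 5 tested members (32 of the 38) were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. With a preset correlation 9 lists were called, 8 higher and 1 lower in KO. With an estimated correlation none was called, nor by fry's directional test (lowest adjusted p = 0.0725), whereas fry's mixed test, which asks for change in either direction, called 18.

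The procedure was tested on 5 simulated data sets of 14925 genes, 2 against 3 libraries, with 200 genes changed in each. It recovered 35.2% of genes changed 1.5-fold, 63.9% of those changed 2-fold and 87.3% of those changed 4-fold, all with the right sign. Of 723 calls 103 were false (14.2%), more than the nominal 5%, so single calls near the threshold are less certain than their adjusted p. The shifted list was recovered and 0 of 30 unshifted lists were called. Genes were simulated independently of each other, so this does not test lists whose genes move together. The estimated correlation was 0.943 for the cell cycle list and 0.375 for the NF-kappa-B list. Alternatives were other scaling factors, a looser and a stricter filter on low counts, DESeq2 1.42.0, limma-voom with and without quality weights, a non-robust dispersion, the replicate number as a block, thinning to the smallest library, a minimum change of 1.5-fold and leaving out each library in turn.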

Results

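Polyadenylated RNA was sequenced from stromal cells of mesenteric adipose tissue, the fat that surrounds the intestinal lymphatics and vessels. The cells came from male mice carrying a floxed EGFR allele, on day 9 of a first infection with H.poly, the common short form of Heligmosomoides polygyrus, a nematode of the mouse small intestine. The titles place 3 libraries in a wild-type group (WT) and 2 in a knockout group (KO). All 5 libraries came from infected mice, so the data hold no comparison with uninfected tissue. The sample descriptions also carry the marker PDGFRa, a receptor of adipose stromal cells. Whether it names the sorting marker or the driver of the deletion is not given in the sources used here. Library totals were 25645996 counts (WT replicate 1), 28710825 (WT replicate 2), 39222470 (WT replicate 3), 25942875 (KO replicate 1) and 33064296 (KO replicate 2). Between 20982 and 22170 genes had at least 1 count per library. Each library carries its own number in the descriptions, but nothing says that each came from a separate animal, so p-values measure the spread between these samples, which may be technical. Xist lay between 0 and 0.273 CPM (counts scaled to a common library size) and the Y-linked Ddx3y between 63.2 and 89.0 CPM, as in male tissue. The most abundant transcript was Gsn, which encodes gelsolin and took 6.36 to 8.46% of the counts.

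The comparison asks how the transcriptome of these stromal cells differs when the EGF receptor gene is targeted, and Egfr itself was examined first. Egfr (ENSMUSG00000020122, chromosome 11, 16752203 to 16918158 in mm10, plus strand, protein-coding) had 2299, 5774 and 3774 counts in WT replicates 1 to 3, against 529 and 774 counts in KO replicates 1 and 2. This corresponds to 89.1, 204 and 95.9 CPM in WT and to 20.5 and 23.2 CPM in KO. The mean was 129.7 ± 64.6 CPM in WT (SD, n = 3) and 21.9 ± 1.91 CPM in KO (SD, n = 2), a ratio of 0.169. Both KO libraries therefore lay below each WT library, in the direction of their labels. The log2 fold change was -2.57 (SE 0.47, 95% confidence interval -3.80 to -1.33), but it did not pass the threshold over all genes (edgeR quasi-likelihood test, adjusted p = 0.111). WT replicate 2 held over 2 times the Egfr of the other WT libraries, and without it the log2 fold change was -2.08 with an adjusted p of 0.00145. Over 15 other settings tried, the adjusted p ran from 3.96e-05 to 0.521, and 5 of them passed. Without a filter on low counts it passed as well, but there edgeR estimated infinite prior degrees of freedom and gave no gene a spread of its own, so that p is not relied on. Counts summed over a gene cannot show which exons were removed, and transcripts that still carry the remaining exons would be counted.

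**Figure D1:**
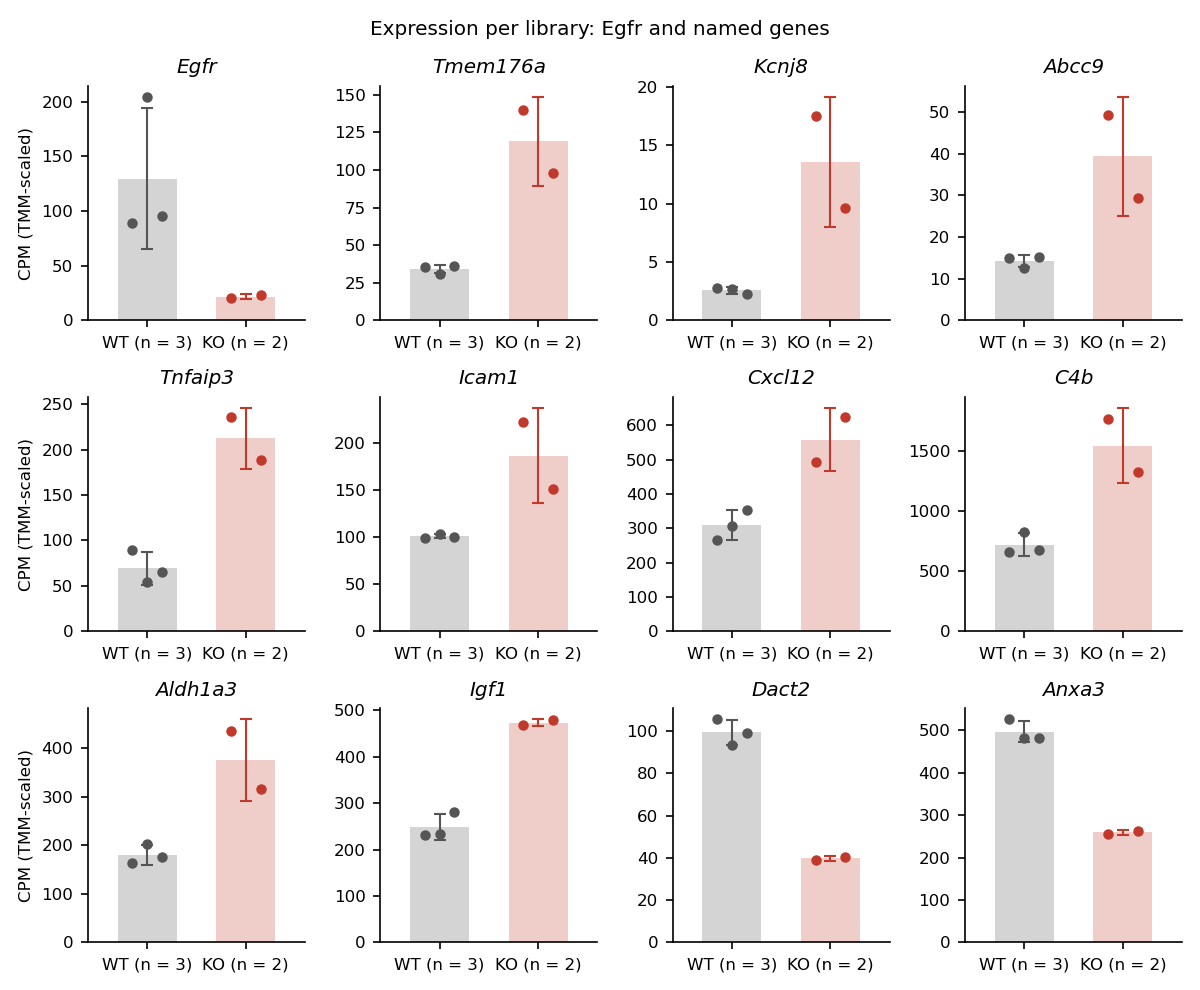
Expression of Egfr and 11 other genes in each library, as CPM scaled by TMM factors (vertical axes, each starting at 0), for 3 WT and 2 KO libraries. Points are libraries, bars are group means and error bars are SD. The KO libraries lie below each WT library for Egfr, Dact2 and Anxa3 and above each WT library for the other genes shown.

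Of 14925 genes tested, 168 differed between KO and WT, with 113 higher and 55 lower in KO (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). Of the 168, 68 changed by over 2-fold (54 higher, 14 lower), and the median absolute log2 fold change was 0.87. Kcnj8, the pore-forming subunit of an ATP-sensitive potassium channel, was among the genes that rose most, and its neighbour Abcc9, which encodes the regulatory subunit, rose less. Kcnj8 (chromosome 6, 142564837 to 142571614) rose 5.29-fold, from 2.57 ± 0.275 CPM in WT (SD, n = 3) to 13.6 ± 5.56 CPM in KO (SD, n = 2). Abcc9 (chromosome 6, 142587862 to 142702315) rose 2.76-fold to 39.4 ± 14.2 CPM (SD, n = 2). Tmem176a and Tmem176b, membrane proteins encoded next to each other between 48833818 and 48847071 on chromosome 6, rose 3.47-fold and 3.14-fold (SE of the log2 fold change 0.15 and 0.14). Their exons overlap on opposite strands over 2.13% of Tmem176a and 3.42% of Tmem176b. Pde4d, a cAMP phosphodiesterase, rose 3.66-fold to 9.89 ± 0.710 CPM (SD, n = 2). The neurotrophin receptor Ngfr (3.31-fold), the adhesion molecule Nfasc (3.01-fold), Syndig1 (3.25-fold) and the TNF receptor family member Tnfrsf19 (3.01-fold) also rose. Serpina3i rose 3.65-fold and Arhgap36 3.34-fold. Serpina3i belongs to a cluster of near-identical protease inhibitor genes, so its reads may be shared with its paralogs. Apart from Tmem176a, Tmem176b and Abcc9, these genes had KO means below 14 CPM. Kcnj8, Pde4d, Tmem176a and Tmem176b passed without each library in turn, and the other genes named here lost their call in at least 1 such fit.

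The genes that fell most were Fam167a, to 0.248 times the WT level, the plexin ligand Sema3e (0.294 times) and the sulfotransferase Chst1 (0.328 times). They were followed by the secreted pentraxin Nptx2 (0.359 times), the membrane protein Islr2 (0.380 times), the GABA transporter Slc6a13 (0.392 times) and the deubiquitinase Uchl1 (0.395 times). Dact2, an intracellular regulator of Wnt and TGF-beta signalling (chromosome 17, 14195052 to 14204304), fell from 99.5 ± 6.01 CPM in WT (SD, n = 3) to 39.8 ± 1.19 CPM in KO (SD, n = 2). It had the smallest adjusted p among the genes chosen by the naming rule (0.00107, edgeR). The vasoconstrictor peptide gene Edn1 (0.405 times), the focal adhesion protein Tes (0.413 times), the chemokine-scavenging receptor Ackr2 (0.449 times) and the adhesion receptor Adgrf5 (0.471 times) completed this group. Apart from Dact2, Islr2 and Uchl1, each of these falling genes lost its call in at least 1 fit that left out 1 library. Uchl1 shares 18.1% and Islr2 3.99% of their exonic bases with other annotated genes, and these libraries do not mark strand. The count of 168 depended on each library, with 65 genes passing without WT replicate 1, 57 without WT replicate 2, 74 without WT replicate 3, 47 without KO replicate 1 and 366 without KO replicate 2. All 168 genes kept their direction in these 5 fits and 28 passed in each of them, among them Dact2, Islr2, Uchl1, Kcnj8, Pde4d, Tmem176a and Tmem176b, whereas Nptx2 and Adgrf5 passed in none.

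**Figure D2:**
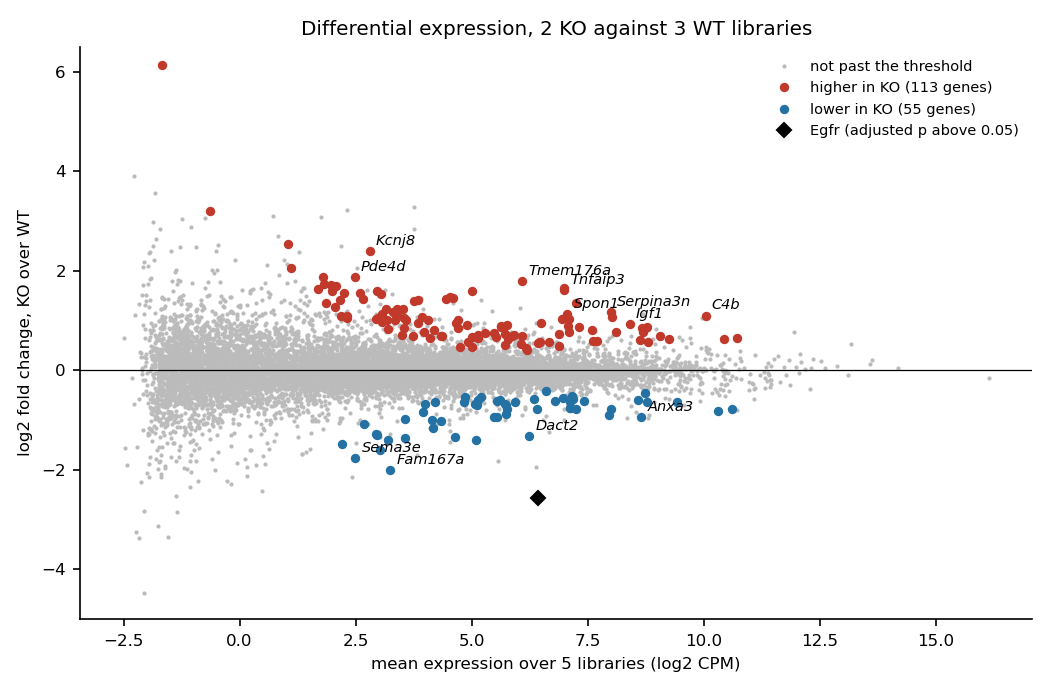
Log2 fold change of KO over WT (vertical axis) against mean expression over the 5 libraries (horizontal axis, log2 CPM) for 14925 genes. Red points are the 113 genes higher and blue points the 55 genes lower in KO at an adjusted p below 0.05, grey points are all other genes, and the black diamond is Egfr, at a log2 fold change of -2.57.

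Chemokines, adhesion molecules and inflammatory cytokines were higher in KO as a group. Of 30 tested members, 26 had a positive log2 fold change, 4 rose over all genes tested and 14 rose adjusted over the list alone. The leukocyte adhesion receptors Vcam1 and Icam1 rose 1.83-fold and 1.85-fold, Vcam1 from 119.5 ± 14.0 CPM in WT (SD, n = 3) to 219 ± 34.9 CPM in KO (SD, n = 2). The chemokines Cxcl12 and Ccl19, which guide leukocytes in lymphoid and stromal niches, rose 1.80-fold to 558 ± 91.8 CPM and 2.67-fold to 7.13 ± 2.48 CPM (SD, n = 2). Of 12 tested feedback genes of the transcription factor NF-kappa-B, 2 rose over all genes and 5 adjusted over the list alone. Those that rose over all genes were Tnfaip3, which encodes the inhibitor A20, at 3.05-fold (log2 fold change 1.61, SE 0.22) and the nuclear inhibitor family member Nfkbiz at 1.55-fold (log2 fold change 0.64, SE 0.11). The remaining 10 did not pass over all genes by edgeR, whereas DESeq2 called 5 of the 12 and limma-voom 2. Of these genes of both lists, Vcam1 passed in 3 of the 5 fits that left out 1 library, Tnfaip3 in 2, Icam1, Cxcl12 and Ccl19 in 1 and Nfkbiz in none. Both lists were called by a competitive set test with a preset correlation (camera, adjusted p = 7.21e-15 and 3.43e-07). Neither call held with an estimated correlation (adjusted p = 0.197 and 0.335), and leaving out 1 library changed neither. Mesothelial marker transcripts were also higher in the KO libraries (summed 262 ± 29.7 CPM, SD, n = 2, against 187 ± 17.4 CPM, SD, n = 3). So were those of lymph node stroma, which include Ccl19 and were mostly Il7 (35.3 ± 7.86 against 18.0 ± 2.83 CPM). Of 38 interferon response genes, by contrast, 30 had a negative log2 fold change (median -0.11) and the list was not called (adjusted p = 0.180). Only Gbp5 (2.08-fold) and Irf1 (1.49-fold) of this list passed by edgeR, and both rose, Gbp5 in 1 and Irf1 in none of these 5 fits, while DESeq2 called 4 and limma-voom 2.

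Genes of retinoid metabolism and of the complement system were higher in KO as well. Of 13 retinoid genes, 3 rose over all genes, 6 rose adjusted over the list alone and the median log2 fold change was 0.57. Aldh1a3, which makes retinoic acid, rose from 180.0 ± 20.0 CPM in WT (SD, n = 3) to 376 ± 83.9 CPM in KO (SD, n = 2). The retinol carrier Rbp4 rose 1.83-fold, and Dhrs3, which reduces retinal to retinol, rose 1.61-fold. Of 18 complement genes, 2 rose over all genes, and 6 rose and 1 fell adjusted over the list alone. C4b rose from 721 ± 93.3 CPM in WT (SD, n = 3) to 1543 ± 312 CPM in KO (SD, n = 2), and Cfb, a component of the alternative pathway convertase, rose 1.87-fold. Both are uncertain as single genes, because C4b has a near-identical neighbour and 79.5% of the exonic bases of Cfb overlap the annotated gene Gm20547. Of the 5 fits that left out 1 library, Aldh1a3 and C4b passed in 2, and Dhrs3 and Cfb in 1. The set test called both lists (camera with a preset correlation, adjusted p = 1.16e-09 for retinoid and 1.41e-06 for complement genes). With an estimated correlation neither was called (adjusted p = 0.264 and 0.335). These lists too moved with the summed mesothelial and lymph node stromal markers, at 1.40 and 1.96 times the WT level in KO. Most of the mesothelial sum is Wt1. Without Wt1 it was 21.1 to 35.6 CPM in WT and 64.6 and 72.6 CPM in KO (scaled by TMM factors).

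Matrix glycoproteins and proteoglycans changed in part, whereas no collagen passed the main test. Of 39 glycoprotein and proteoglycan genes, 4 rose over all genes, and 8 rose and 5 fell adjusted over the list alone. Spon1 rose 2.18-fold to 198 ± 19.0 CPM, Podn 1.72-fold to 183 ± 18.5 CPM, Spon2 1.55-fold to 1758 ± 176 CPM and Emilin1 1.53-fold to 496 ± 63.1 CPM (SD, n = 2), the last 3 in 1 of the 5 fits that left out 1 library. The list was called with a preset correlation (camera, adjusted p = 0.0285) but not with an estimated one (adjusted p = 0.335). The call was also lost without WT replicate 2 (adjusted p = 0.0991) and without KO replicate 2 (adjusted p = 0.284). Of 18 fibrillar and associated collagens, none passed over all genes by edgeR and 1 fell adjusted over the list alone (Col12a1, log2 fold change -0.61, adjusted p over all genes = 0.101). Of these collagens 3 had an unadjusted p below 0.05, DESeq2 called 1 and limma-voom 0. Of 22 basement membrane genes, none passed over all genes by edgeR, and 2 were higher and 2 lower adjusted over the list alone (6 at an unadjusted p below 0.05, 4 by DESeq2 and 0 by limma-voom). Of 35 crosslinking and remodelling genes, 1 passed over all genes, the hyaluronan synthase Has2, which fell to 0.562 times the WT level and passed in 1 of those 5 fits. Adjusted over the list alone 1 was higher (Loxl4) and 2 were lower (Has2 and Timp3), with 13 at an unadjusted p below 0.05, 7 called by DESeq2 and 1 by limma-voom. Of 30 TGF-beta ligands, receptors and targets, none passed by edgeR over all genes or adjusted over the list alone (10 at an unadjusted p below 0.05, 2 by DESeq2 and 0 by limma-voom). None of these 4 lists was called by camera (adjusted p = 0.851, 0.949, 0.551 and 0.221, in the order given). Fry's mixed test, which asks for change in either direction, called the last 3 (adjusted p = 0.0241, 0.0195 and 0.0241). It did not call the fibrillar and associated collagens (adjusted p = 0.125).

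Of 20 alarmins and genes of type 2 inflammation, 1 rose over all genes (Cish, a feedback inhibitor of cytokine receptor signalling, 1.39-fold, in none of the 5 fits that left out 1 library) and 5 rose adjusted over the list alone. Il33, which encodes an alarmin made by stromal cells, was at 620.0 ± 183 CPM in WT (SD, n = 3) and 1135 ± 90.9 CPM in KO (SD, n = 2), a log2 fold change of 0.87 that did not pass over all genes (edgeR, adjusted p = 0.155). The list median was near zero (0.06) although the list was called higher (camera, adjusted p = 0.0474). The call was lost with an estimated correlation (adjusted p = 0.335), with upper quartile factors (0.0537), with a stricter filter on low counts (0.243) and without KO replicate 2 (0.677). Of 19 glycolysis genes, 1 rose over all genes, the phosphofructokinase Pfkl (1.75-fold, in 1 of those 5 fits), and 2 rose adjusted over the list alone. That list was called higher with a preset correlation (adjusted p = 0.00429) and not with an estimated one (adjusted p = 0.335). Cell cycle genes formed the single list called lower (camera, adjusted p = 0.0346), with a negative log2 fold change in 31 of 35 members and a median of -0.36. No member passed over all genes or adjusted over the list alone by edgeR, at an unadjusted p below 0.05, or by DESeq2 or limma-voom. The example with the smallest p, Rrm1, had a log2 fold change of -0.44 (SE 0.24). The call was lost with an estimated correlation (adjusted p = 0.783), with a stricter filter on low counts (adjusted p = 0.0749) and without WT replicate 1 (adjusted p = 0.923), and without KO replicate 1 the direction turned (adjusted p = 0.117).

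**Figure D3:**
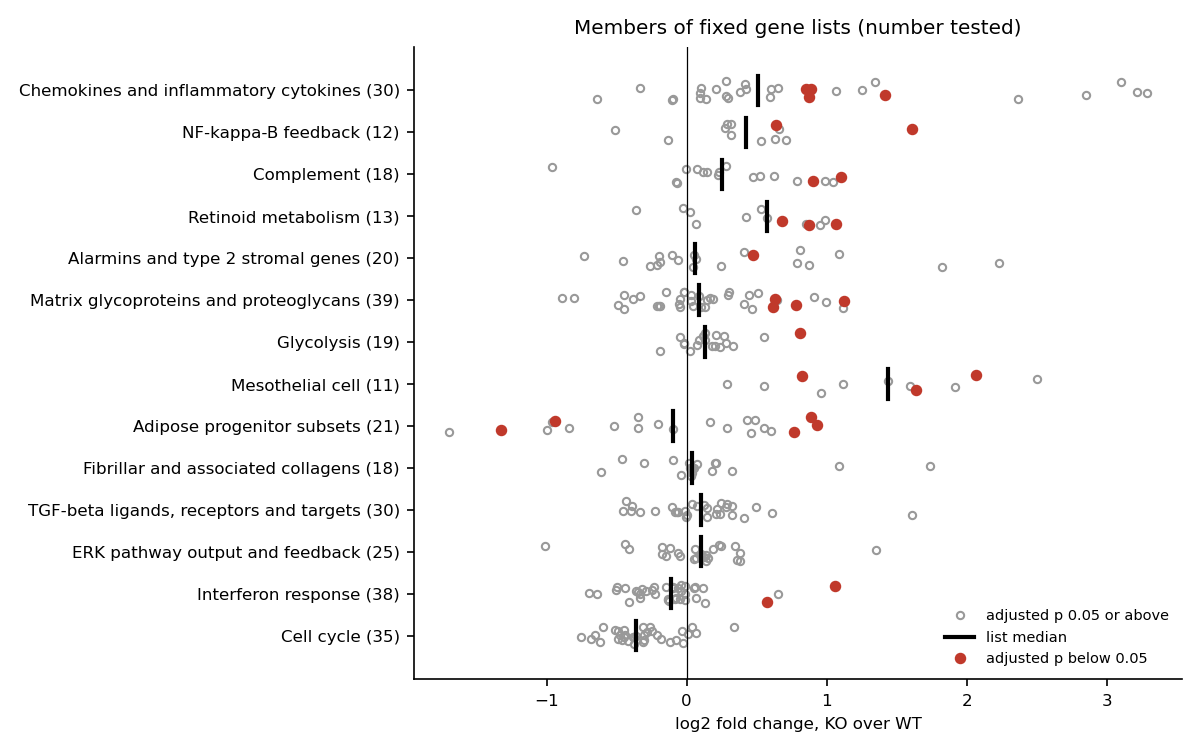
Log2 fold change of KO over WT (horizontal axis) for each tested member of 14 gene lists fixed before the data were examined, with the number of tested members in parentheses. Filled red points passed over all genes, open points did not, and black bars are list medians, which run from -0.36 for cell cycle genes to 1.44 for mesothelial markers.

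Markers of adipose progenitor subsets moved in both directions. Of 21 markers, 3 rose and 2 fell over all genes, and 8 rose and 6 fell adjusted over the list alone. Anxa3 fell from 497 ± 25.3 CPM in WT (SD, n = 3) to 259 ± 5.60 CPM in KO (SD, n = 2), and Dact2 fell as given above. Both are known from progenitors that express Dpp4 and Pi16. Dpp4 itself was at 115 ± 12.1 CPM in WT (SD, n = 3) and 57.7 ± 16.8 CPM in KO (SD, n = 2), a ratio of 0.502 that did not pass over all genes (edgeR, adjusted p = 0.0686). Nor did Pi16, at 2796 ± 514 CPM in WT (SD, n = 3) and 2202 ± 297 CPM in KO (SD, n = 2), a ratio of 0.787 with overlapping groups (edgeR, adjusted p = 0.464). Igf1, a growth factor, rose from 248 ± 28.3 to 473 ± 7.86 CPM (SD), the receptor tyrosine kinase ligand Gas6 rose from 323 ± 17.5 to 550.2 ± 115 CPM (SD), and Icam1, known from committed preadipocytes, rose as described. As a list the markers had no single direction (camera, adjusted p = 0.551). Of 31 growth factors of stromal cells, those that rose over all genes included Igf1, and 5 rose and 4 fell adjusted over the list alone (camera, adjusted p = 0.103). Of 23 genes of adipogenesis and lipid storage none passed over all genes by edgeR, 4 had an unadjusted p below 0.05, DESeq2 called 1, limma-voom 0, and 1 was higher adjusted over the list alone (camera, adjusted p = 0.551). Dact2, Anxa3, Igf1 and Rbp4 passed in each of the 5 fits that left out 1 library, Spon1 in 4 of them, and Gas6 and Icam1 in 1.

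No gene of the EGF receptor pathway passed over all genes by edgeR. Of 11 tested receptors of the family and direct regulators, 1 was lower adjusted over the list alone (Egfr), 2 had an unadjusted p below 0.05, and DESeq2 and limma-voom each called 1. Of 6 tested ligands, none passed either way or by DESeq2 or limma-voom, 2 had an unadjusted p below 0.05, and Tgfa was at 5.34 ± 0.686 CPM in WT (SD, n = 3) and 7.72 ± 1.15 CPM in KO (SD, n = 2). Of 25 output and feedback genes of the ERK pathway, none passed over all genes by edgeR and 3 were higher adjusted over the list alone (Phlda1, Epha4 and Ier3), where 5 had an unadjusted p below 0.05, DESeq2 called 2 and limma-voom 0. Phlda1 was at 283 ± 14.8 CPM in WT (SD, n = 3) and 368 ± 12.1 CPM in KO (SD, n = 2), with 33.0% of its exonic bases shared with another annotated gene. None of these 3 lists was called by camera (adjusted p = 0.295, 0.180 and 0.400, in the order given). By fry's mixed test, which asks for change in either direction, all 3 were called (adjusted p = 0.0229, 0.0195 and 0.0195). That test called 18 of the 32 lists. For the receptor family the mean log2 fold change was -0.28 and the median 0.03, so their signs differ. That list includes the targeted gene Egfr (-2.57), so its mean and its mixed call may largely restate the lower Egfr. The list was not tested without Egfr. Of 21 cholesterol synthesis genes none passed either way or by DESeq2 or limma-voom, 1 had an unadjusted p below 0.05, and the list was not called (adjusted p = 0.530). For scale, 1877 of the 14925 genes had an unadjusted p below 0.05 in the same edgeR test, and DESeq2 called 611 genes where edgeR called 168.

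The libraries were strongly stromal, and markers of other cell types were low. The 15 stromal identity markers summed to 116447 ± 8972 CPM in WT (SD, n = 3) and 110775 ± 847 CPM in KO (SD, n = 2). None of the 15 passed by edgeR or limma-voom, 2 had an unadjusted p below 0.05 and DESeq2 called 1. Of 11 mesothelial markers all were positive, 3 rose over all genes and 9 rose adjusted over the list alone. Krt8, Krt19 and Cldn15 rose 4.18-fold, 3.10-fold and 1.77-fold, to 3.97 ± 1.39, 5.44 ± 0.0698 and 12.3 ± 1.03 CPM (SD, n = 2), and Wt1, which makes up most of the summed signal, was at 158 ± 13.7 CPM in WT and 193 ± 26.6 CPM in KO. Krt19 and Cldn15 passed in 1 and Krt8 in none of the 5 fits that left out 1 library. The mesothelial list was called (camera, adjusted p = 1.42e-13) but not with an estimated correlation (adjusted p = 0.335). Of 12 pericyte and smooth muscle markers, Kcnj8 and Abcc9 rose and the intermediate filament gene Des fell (0.644 times the WT level). The list summed to 75.7 ± 3.17 CPM in WT and 96.7 ± 11.6 CPM in KO. Within that sum Abcc9 went from 14.2 to 39.4 CPM and Kcnj8 from 2.57 to 13.6 CPM. By contrast, 7 of the 12 markers were negative (median log2 fold change -0.11), so the higher sum does not stand for the list. Of the 4 tested markers of lymph node stroma all were positive and Ccl19 rose, with sums of 18.0 ± 2.83 and 35.3 ± 7.86 CPM. Il7 made up most of these sums, at 13.3 ± 2.42 CPM in WT and 23.4 ± 5.03 CPM in KO. It did not pass over all genes (edgeR, adjusted p = 0.0854). Endothelial markers summed to 201 ± 2.78 CPM in WT and 150.4 ± 16.1 CPM in KO. None of 12 was past the threshold by edgeR or limma-voom, with 3 at an unadjusted p below 0.05 and 2 called by DESeq2. Tek made up most of that sum, at 184 ± 3.73 CPM in WT and 130 ± 23.8 CPM in KO. Of the 12 markers 9 were negative and 3 positive, among them Flt1, at 4.29 ± 1.02 and 10.5 ± 6.33 CPM. Adipocyte markers summed to 30.01 ± 3.86 and 45.5 ± 10.7 CPM, and Schwann cell and neuron markers to 50.7 ± 1.86 and 41.8 ± 3.51 CPM, with Ncam1 higher (1.92-fold) and Uchl1 lower.

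Leukocyte markers were at 42.9 ± 7.61 CPM in WT (SD, n = 3) and 53.7 ± 1.83 CPM in KO (SD, n = 2), and macrophage and monocyte markers at 67.7 ± 36.6 and 78.7 ± 1.19 CPM. Markers of T cells and innate lymphoid cells, which include the stromal gene Thy1, summed to 86.0 ± 16.6 and 66.0 ± 16.4 CPM, those of B cells to 15.1 ± 10.2 and 18.5 ± 14.9 CPM, and those of epithelial cells to 14.4 ± 2.20 and 14.6 ± 2.33 CPM. Mast cell, eosinophil and neutrophil markers (0.801 and 1.504 CPM), erythroid markers (1.07 and 1.46 CPM) and pancreatic acinar markers (0.405 and 0.742 CPM) were the lowest. No tested member of these 8 lists passed over all genes by edgeR, DESeq2 or limma-voom, but few were abundant enough to be tested. These were 12 leukocyte, 15 macrophage and monocyte, 3 T cell, 5 B cell, 4 epithelial, 2 erythroid, 1 pancreatic and 0 granulocyte markers, so the smaller lists say little. An unadjusted p below 0.05 was reached by 2 leukocyte, 2 macrophage and monocyte and 1 epithelial marker and by none of the others. The groups did not overlap for the mesothelial, pericyte, lymph node, endothelial, adipocyte, Schwann cell and granulocyte sums, each with a two-sided exact permutation p of 0.1, the smallest that 3 against 2 libraries allow. Nor did they for the leukocyte and pancreatic sums (exact permutation p = 0.2 each). Dissociation and heat shock genes summed to 40007 ± 70.8 CPM in WT and 40797 ± 1973 CPM in KO, with none of 20 past the threshold by edgeR or limma-voom, 4 at an unadjusted p below 0.05 and 2 called by DESeq2 (exact permutation p of the sums = 0.7). Ribosomal protein mRNAs summed to 13595 ± 972 and 13249 ± 224 CPM. Mitochondrially encoded mRNAs took 0.334% of the counts in WT replicate 1 and 0.131 to 0.179% in the other libraries. None of the quality lists was called (camera adjusted p = 0.375 for dissociation, 0.0605 for ribosomal and 0.212 for mitochondrial mRNAs).

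**Figure D4:**
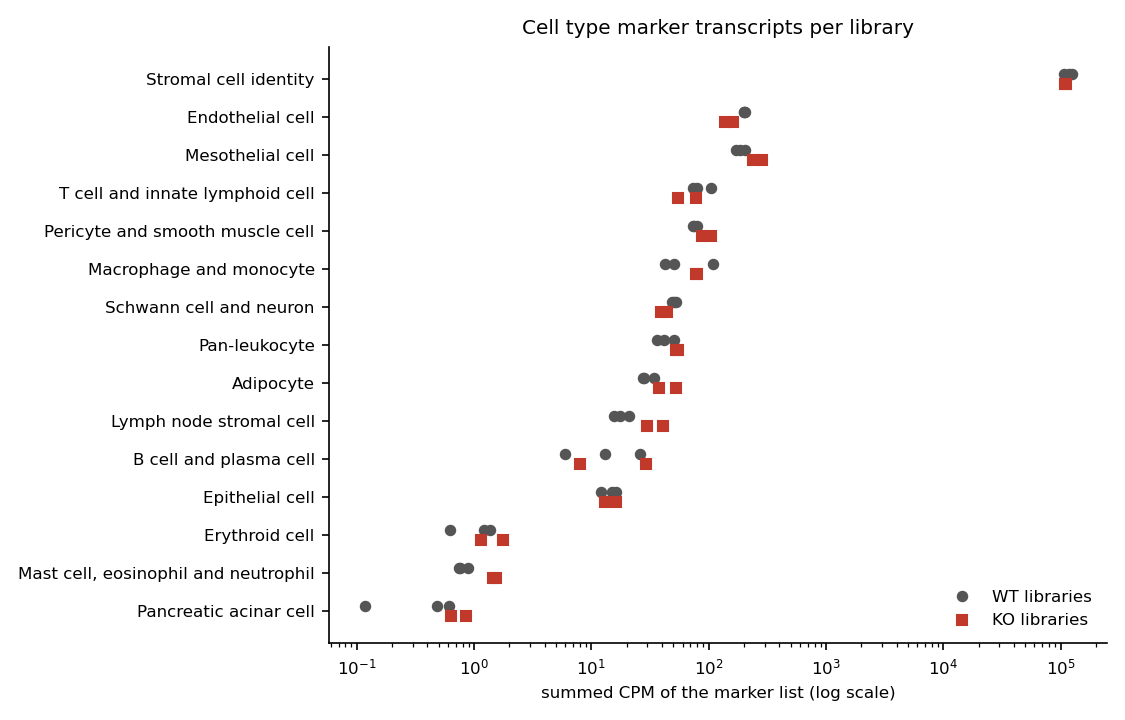
Summed CPM of the marker transcripts of 15 cell types (horizontal axis, log scale) in each library, with grey circles for 3 WT and red squares for 2 KO libraries. Stromal markers lie between 106756 and 124463 CPM and mesothelial markers between 172 and 283 CPM, with both KO libraries above the WT libraries.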

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

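All alternatives were planned before the data were examined. The direction of Egfr and of all 168 called genes was kept in each setting in which they were tested. The count of changed genes stayed within 1.5 times the main count (168, with 113 higher and 55 lower) under other scaling factors, a stricter filter, a non-robust dispersion, both limma-voom fits and thinning, where it ran from 162 to 193. Without a filter on low counts 1066 genes passed (643 higher, 423 lower). There edgeR estimated infinite prior degrees of freedom for all 25930 genes, so that no gene kept a spread of its own, and these p-values are not relied on. DESeq2 called 611 (379 higher, 232 lower), including 167 of the 168, and the cause was not tested. A test against a change of 1.5-fold called 11 genes (8 higher, 3 lower), since it asks for more than a difference from zero. Leaving out each library in turn gave 47 to 366 genes (35 to 231 higher, 12 to 135 lower). With a lone KO library, the spread was taken from the WT libraries. Each of these fits also has fewer residual degrees of freedom than the main test, so calls can be lost through lower power alone. The lowest count came without KO replicate 1 and the highest without KO replicate 2.

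Egfr did not pass over all genes in the main test (adjusted p = 0.111). It passed with a non-robust dispersion (log2 fold change -2.57, adjusted p = 0.0258), with DESeq2 (-2.57, 3.96e-05), with limma-voom (-2.46, 0.0275), with quality weights (-2.57, 0.0329) and without WT replicate 2 (-2.08, 0.00145), the WT library with the most Egfr. In the main test Egfr had 1.68 prior degrees of freedom, against a mean of 5.57 over genes. Its spread was therefore moderated less by other genes than usual. Whether this accounts for each of these differences was not tested. The fit without a filter gave -2.56 with an adjusted p of 9.80e-107, which is not relied on for the reason given, as its SE was 0.114 against 0.470 in the main test. Leaving out each library gave log2 fold changes from -2.77 to -2.08. For 89 single genes, apart from that fit, 1088 of 1328 values kept their side of the threshold, 223 no longer passed, 17 newly passed and none reversed.

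Of the 9 gene lists called, none was called with an estimated correlation (0 lists) or by fry's directional test (0 lists). Leaving out each library gave 9 to 15 lists, the 15 without WT replicate 3. Apart from the estimated correlation and fry, and with the left-out libraries included, 100 of 108 list values kept their call and 8 lost it. Cell cycle genes turned to higher in KO without KO replicate 1 (adjusted p = 0.117), and over the fits that left out 1 library their adjusted p ran from 2.60e-10 to 0.923. The summed dissociation genes were at 1.02 times the WT level on either scale of CPM.

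The numbers 1 and 2 occur in both groups, but nothing shows that they pair the libraries. Deviations from the group means correlated at -0.0220 for the libraries numbered 1 and -0.0685 for those numbered 2. The 2 KO libraries deviate equally in opposite directions. The values of the same WT libraries with the other KO library (0.0220 and 0.0685) are therefore fixed and are no separate check. With the replicate number as a block 84 genes passed (58 higher, 26 lower), 57 of them among the 168, and 15 lists were called. The pairing leaves WT replicate 3 without a partner, so that library adds nothing to the difference in that fit. The block also leaves fewer residual degrees of freedom than the main test, so the lower count need not reflect pairing. Thinning to the smallest library gave 185 genes.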

Other observations

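The gene groups of the first paragraphs and the tests of neighbouring genes, of dissociation stress, of lymph node stroma and of the progenitor subset were chosen after the results were seen. Of 9 tested receptors of the interleukin 6 family, 3 rose over all genes and 7 adjusted over the list alone. The leptin receptor Lepr rose 2.02-fold to 23.9 ± 0.702 CPM, the ciliary neurotrophic factor receptor Cntfr 2.02-fold and the oncostatin M receptor Osmr 1.51-fold to 244 ± 34.5 CPM (SD, n = 2). The interleukin 1 receptor Il1r1 rose from 86.8 ± 9.16 CPM in WT (SD, n = 3) to 179 ± 26.1 CPM in KO (SD, n = 2). Serpina3n, an acute phase protease inhibitor, rose from 169 ± 4.18 to 382 ± 12.9 CPM (SD), and all 7 tested genes of its cluster were positive, although these paralogs can share reads. Il1r1 and Serpina3n passed in each of the 5 fits that left out 1 library, and Lepr, Cntfr and Osmr in 1. Neurotrophin receptors and neural adhesion molecules were positive in all 11 tested members, and 5 rose over all genes, among them Ngfr, Nfasc and Ncam1, whereas the Schwann cell and neuron markers as a list were not called (camera, adjusted p = 0.675).

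Genes of further groups fell in KO. Of 9 S100 calcium-binding proteins 3 fell, S100a10 to 0.662, S100a11 to 0.648 and S100a13 to 0.753 times the WT level, S100a10 from 445 ± 6.31 CPM (SD, n = 3) to 295 ± 16.9 CPM (SD, n = 2). Of the 5 fits that left out 1 library S100a10 passed in 2, S100a11 in 1 and S100a13 in none. Of 10 annexins, some of which bind S100 proteins, 1 fell (Anxa3) and 8 were negative. Of 24 focal adhesion and actin linker genes 4 fell, including Tes, and 1 rose, and of 30 axon guidance genes 2 fell and 2 rose, so that group had no single direction. Because these groups were picked from genes already seen to change, their set tests carry no independent evidence. The subunit Polr2a of RNA polymerase II rose 1.69-fold (log2 fold change 0.76, SE 0.08) and passed without each library in turn. Called genes formed 3 neighbouring pairs within 100 kb (S100a10 with S100a11, Tmem176a with Tmem176b, Kcnj8 with Abcc9), against a mean of 0.852 in 10000 shuffles (permutation p = 0.0552). Of 60 other tested genes within 10 Mb of Egfr, 0 were called by edgeR or limma-voom and 2 by DESeq2, and 7 had an unadjusted p below 0.05.

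Egfr in WT replicate 2, at 204 CPM, lay above the other WT libraries (89.1 and 95.9 CPM). General variability of that library is argued against, since 0.0641% of genes of 50 to 500 CPM (2 of 3118) deviated by at least the Egfr value. Egfr itself is among these 2. A candidate explanation is that WT replicates 1 and 3 had less Egfr with the KO-responsive genes following the dose. On the axis from KO (0) to the other WT libraries (1), genes called without WT replicate 2 placed it at a median of 0.946. The 95% interval over genes was 0.878 to 1.04, so its genes did not lie beyond those of the other WT libraries by more than the spread between genes. Held out in the same way, WT replicate 1 lay at 0.984 (0.869 to 1.06) and WT replicate 3 at 0.863 (0.839 to 0.895). Selecting the genes without a library can make it fall short of 1, but how much was not tested. The interval of WT replicate 2 includes 1 and holds no spread between libraries. Whether dose matters therefore cannot be told apart from chance with these libraries.

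Some chemokine, NF-kappa-B, complement and retinoid genes (11 called in all) rose alongside higher summed markers of mesothelial cells and of lymph node stroma. The dissociation and heat shock genes had a median log2 fold change of -0.169 (95% interval over genes -0.272 to 0.0379). That is below 0.442, which is 50% of the median change of the 11 called genes of the pattern. A rise of that size was therefore not seen in these genes as a set. The interval resamples genes of the same 5 libraries and holds no spread between libraries. Their summed CPM was 42192 and 39402 in KO replicates 1 and 2, against 39946 to 40084 in WT. More stress in KO replicate 1 cannot be excluded. More mesothelial or lymph node stromal cells in the KO libraries may contribute. Within groups, the 11 genes followed the mesothelial sum (21.1 to 35.6 CPM in WT and 64.6 and 72.6 CPM in KO, without Wt1, which stromal cells also express) with a median of 0.272 of the slope needed (95% interval -0.384 to 0.793). For the lymph node stromal sum without Ccl19 (13.05 to 17.9 CPM in WT and 31.9 and 23.7 CPM in KO) the median was 0.547 (95% interval -0.517 to 0.785). Most of that sum is Il7. Both intervals resample the 11 genes and not the libraries, so their width shows disagreement between genes and holds no spread between libraries. With 5 libraries, mesothelial cells, lymph node stromal cells and a change within stromal cells that follows from the knockout cannot be told apart.

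Dact2 and Anxa3 fell while Igf1, Gas6 and Icam1 rose, markers of different progenitor subsets. The other 12 markers of the Dpp4 and Pi16 subset were all negative, as a smaller share of that subset in KO would give. None of the 12 passed over all genes by edgeR. Their median log2 fold change was -0.901 (95% interval over markers -1.12 to -0.373), and 8 of them had an interval below 0. The interval of the median holds no spread between libraries. Dpp4, Cd55, Bmp7, Sema3c and Wnt2 belong to the progenitor list already described, so they add no separate evidence. Whether a smaller share is the whole cause cannot be told. The log2 fold changes of the 14 markers differed, from -1.95 to -0.34, with 84.0% of the variance between them beyond their errors, but markers also expressed by other cells would fall less. A change of expression within the subset stays open, and so does the gate used to isolate the cells, which was not tested.

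Of the 10 splits of the 5 libraries into 3 and 2, 1, the real one, gave as many as 168 genes, and the highest of the others gave 0. So few splits cannot give a share under 0.05.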
